A study of Triticum aestivum with 24 samples.

How the data were processed

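The samples are leaf RNA from 4 genotype labels of wheat under 2 water regimes, with 3 libraries in each of the 8 groups. Per the labels' protocols, plants were grown at 80% field capacity until 4 weeks old and water was then withheld for 12 days; the day on which leaves were taken for RNA is not given in the sources used here. All libraries carry the same batch label. Per the labels, RNA was purified on columns, libraries were made with a TruSeq kit, and both ends of fragments were sequenced with 150 cycles on a NovaSeq instrument. The series' design text speaks of 27 samples, of re-watered plants and of other genotype names, which does not match the 24 sample labels; groups were taken from the sample labels.

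The deposited values are normalized counts, a signal per gene that the authors scaled between libraries, though not to a common sum. The submitters' processing notes list CASAVA, Trimmomatic, STAR, Salmon and DESeq2, without versions, and the genome build and annotation release are not given in the sources used here. The values are not whole numbers. Genes with a value in 1 library only step by a fixed amount, the value of 1 read, which lay between 0.651 and 1.54 across libraries; 93.0% to 99.5% of these genes were whole multiples of it within 0.01. Over all genes 2.03% to 12.9% were, so whole reads could not be recovered for most genes and no count model was fitted. Dividing the sum of values by this step gave the estimated depth of 33700000 to 55300000 reads per library. A count of 0 then allows up to 3 reads, a value of 1.95 to 4.63 depending on the library, and such floors cover counting error only. The authors' scaling makes library sums differ, from 32500000 to 54400000, while the median of genes above 0 in every library stayed between 177.4 and 185.2.

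None of the 107891 identifiers matched the table of 155467 named wheat genes (assembly IWGSC CS RefSeq v2.1) used for names, so the 30 gene lists fixed before the data were examined had 0 matched members, and neither they nor the level of TOR could be tested. The tests of the gene lists and of TOR are not reported here. Chromosome and gene order were read from the identifiers, and no coordinates are given. Reads of the A, B and D copies of a gene are similar, and the authors' quantification could divide them between copies, so values of single copies are uncertain to that extent.

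In R 4.3.3, values were taken as log2(value + 1) and genes with at least 10 in at least 3 libraries were kept, which left 60088; 24378 identifiers were 0 throughout. A single limma 3.58.1 fit of the 8 groups, with an intensity trend and a robust prior, gave 13 comparisons: drought in each of 4 genotypes, each of 3 lines against WT in both regimes, and the 3 differences of drought effects. Tests were two-sided, with a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Fold changes on the log2(value + 1) scale understate the change of low genes. Tables were handled with the data.table package (version 1.17.8).

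Named genes follow a rule fixed before the data were examined: without gene names, at most 2 identifiers that rose and 2 that fell in each comparison, those with the largest change among genes past the threshold whose groups did not overlap and whose mean reached 50 in the higher group. The most abundant genes were ranked by the mean normalized count over all 24 libraries unless stated. The 3 most abundant genes, the genes that bound a segment and the gene set of 1 library were chosen after their values were seen. A fold against a group at 0 was computed with 3 reads in each library of that group; a fold against 1 to 3 reads is given with its 95% Poisson counting interval; other folds are ratios of group means.

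The scan along chromosomes was chosen after the data were seen. It used genes with a mean of at least 30, cut into non-overlapping windows of 30 genes, and took the group's log2 mean minus the median of the 4 groups of its regime. A run starts at a window median of 0.6 and extends while it stays at 0.3 or more; runs of at least 3 windows are called segments, and overlapping runs of different groups were joined into 1 segment. Differences of a segment's drought effect between genotypes were tested by exact permutation of the labels within each regime.

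The limma step was tested on simulated data with 200 changed genes among 60088. For a drought comparison it recovered 75% of the 2-fold and 93% of the 4-fold changes, for a line against WT 76% and 94%, and for a difference of drought effects 59% and 80%; of the calls 5.1%, 7.1% and 6.7% were false. The simulated noise was independent between genes and had the spread of the fit. Sets of genes that vary together between libraries, and changes as wide as those called here, were not simulated. These shares therefore need not hold for the comparisons below. The segment scan recovered a planted run of 3 windows at -0.8 in shuffled genes and called 0 others.

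Alternatives were other pseudocounts, filters and scalings, limma without the trend, a fit of only the compared libraries, the replicate number as a block, a minimum of 2-fold, and each library left out in turn. Leaving out the genes of the 4 segments, and ranking the most abundant genes in other libraries than all 24, were added after the data were seen.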

Results

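Gene expression was measured by RNA sequencing of wheat leaves (Triticum aestivum, a hexaploid with the subgenomes A, B and D) from the spring line Fielder, labelled WT, and from 3 transgenic lines of it. TOR (target of rapamycin) is a protein kinase that links nutrient and energy supply to growth. The transgenic lines carry a wheat TOR gene and are labelled UBQ, DREM and DEH2 after the prefixes of their construct names. Each of the 4 genotype labels has 3 well-watered and 3 drought libraries, which makes 8 groups and 24 libraries. The deposited values were normalized counts for 107891 gene identifiers. Their sum per library ranged from 32500000 to 54400000, and the step that 1 read makes in each library put the depth at about 33700000 to 55300000 reads. A total of 60088 genes reached a value of 10 in at least 3 libraries and were tested. Libraries of a group correlated across genes at r = 0.974 to 0.986, and libraries of different groups at 0.735 to 0.969. The labels number the replicates and do not say whether they came from separate plants, so the p-values measure the spread between these samples, which may be technical.

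The gene identifiers name the chromosome and the order along it, and none of them matched the table of gene names used here. Genes are therefore given by identifier, no pathway is named, and the level of TOR itself, which would check the genotype labels, was not analysed here. The groups are called by their labels throughout, because expression along parts of chromosomes 1B and 2A went against the genotype labels, as described next.

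The first question was whether libraries of 1 genotype label shared genotype-specific expression in both water regimes. Medians over windows of 30 neighbouring genes were compared with the median of the 4 groups of the same water regime. At the start of chromosome 1B, from TraesCS1B02G000600 to TraesCS1B02G084600, expression was almost lost in the libraries labelled DEH2 well-watered, with a median log2 deviation of -4.97 over 210 genes, and in those labelled DREM drought, with -4.88. The same genes lay at 0.19 in DEH2 drought and at 0.10 in DREM well-watered. The 3 libraries of DEH2 well-watered had medians from -5.18 to -5.02, those of DREM drought from -5.20 to -4.42, and the libraries of the other 6 groups lay between -0.02 and 0.21. Within this segment 91.0% of the genes were lower by at least 0.3 in DEH2 well-watered and 93.3% in DREM drought, against 23.3% and 25% of the 60 genes that follow it.

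On chromosome 2A expression was lower in 2 other groups. In UBQ well-watered 1 run reached from TraesCS2A02G238400 to TraesCS2A02G590600, and in WT drought there were 2 runs, from TraesCS2A02G238400 to TraesCS2A02G299600 and from TraesCS2A02G304300 to TraesCS2A02G562000. The longest run, with 1470 genes in the windows, is taken as the 2A segment for all groups. Its median log2 deviation was -0.77 in UBQ well-watered and -0.71 in WT drought, and it was 0.06 in UBQ drought and 0.04 in WT well-watered. The library medians ran from -0.78 to -0.76 and from -0.72 to -0.69 in the lower groups. On chromosome 6B the segment from TraesCS6B02G000100 to TraesCS6B02G096400 was almost lost in UBQ drought alone, at a median of -4.03 over 240 genes, with library medians from -4.12 to -3.96; in UBQ well-watered it lay at -0.05. The segment from TraesCS4B02G352100 to TraesCS4B02G398200 was higher in UBQ drought alone, at 0.75 over 120 genes, and lay at -0.03 in UBQ well-watered. The edges on 2A and 4B were less sharp than on 1B: of the 69 genes beside the 2A segment 49.3% were lower by at least 0.3 in UBQ well-watered and 53.6% in WT drought, against 83.6% and 70.1% within it, and of the 67 beside the 4B segment 38.8% were higher by as much in UBQ drought, against 78.3% within. Beside the 6B segment it was 20% of 60 genes, against 89.6%. In 100 random orders of the genes no window of any group passed 0.587. These 4 segments held 2798 of the tested genes, or 4.66%.

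**Figure D1:**
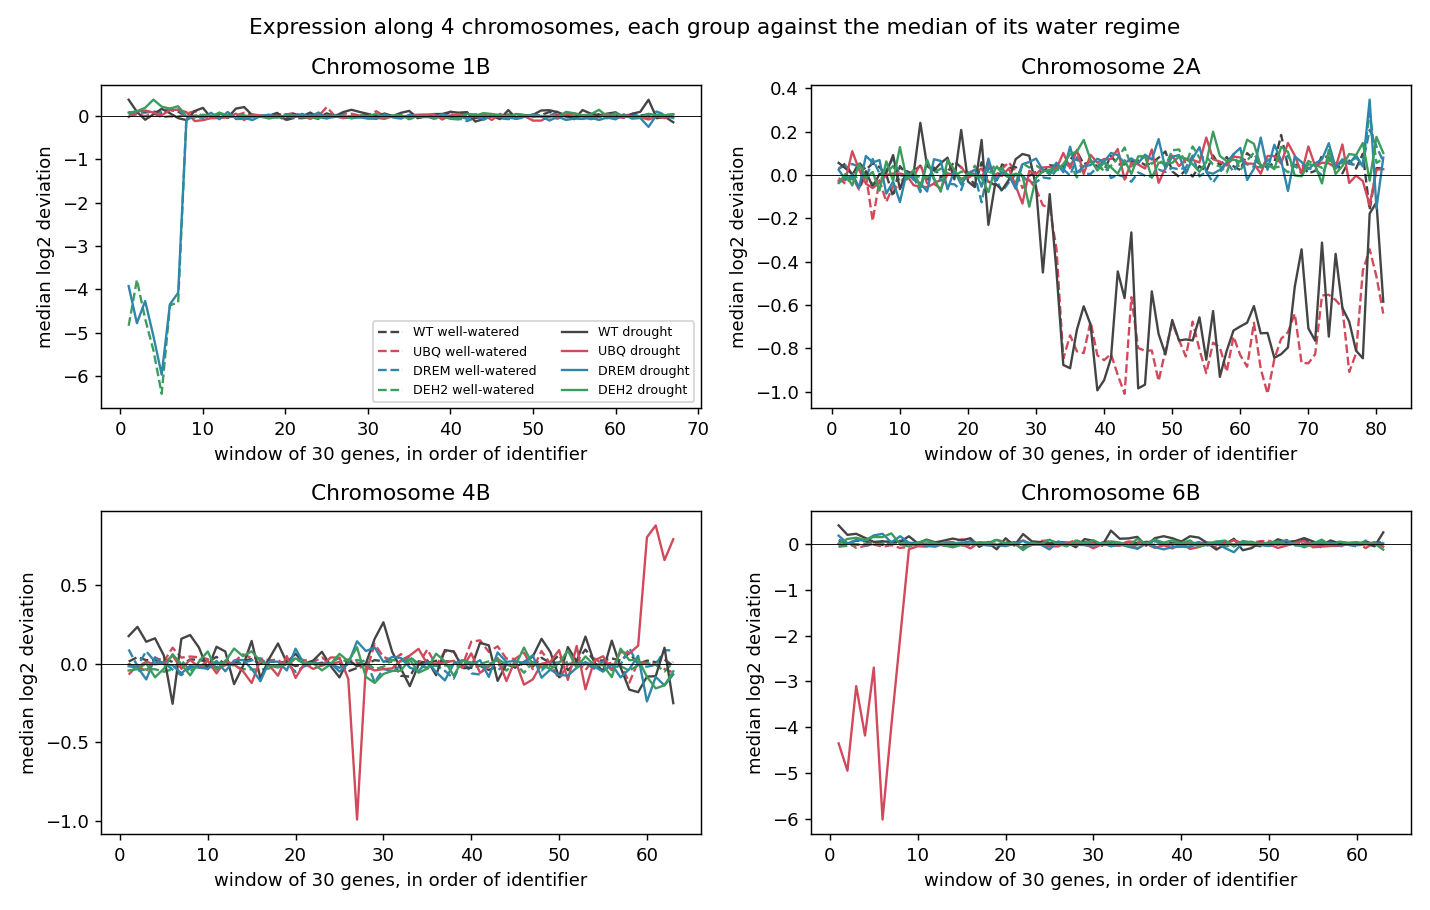
Median log2 deviation of each group from the median of the 4 groups of its water regime, in windows of 30 neighbouring genes along chromosomes 1B, 2A, 4B and 6B (dashed lines well-watered, solid lines drought; colours give the genotype label; vertical scales differ between panels). The 1B segment is low in DEH2 well-watered (-4.97) and DREM drought (-4.88), the 2A segment in UBQ well-watered (-0.77) and WT drought (-0.71), and the 6B segment in UBQ drought (-4.03).

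Together with shorter runs there were 8 such regions. Of these 4 were found in groups of different genotype labels, 4 in 1 group, and 0 in both groups of 1 genotype label. The shorter runs shared by DEH2 well-watered and DREM drought were higher ones on 3A, from TraesCS3A02G464400 to TraesCS3A02G480600, and on 3D, from TraesCS3D02G525700 to TraesCS3D02G540100. Complete presence and absence gave the same pattern for 1B and 6B: 40 genes were under 3 reads in every library of DEH2 well-watered and DREM drought and at 30 or more in all other libraries, 32 of them on 1B. A further 43 genes were absent in this sense from UBQ drought alone, 40 of them on 6B. From UBQ well-watered and WT drought together, the groups with the lower 2A segment, 1 gene was absent, and it was on 2D. The comparisons below include genes of these segments, and the numbers called are given for those comparisons in which a segment was shifted in 1 of the groups. If the 2 groups of a label came from unlike plants, comparisons between water regimes would hold such differences outside the segments too.

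The second question was how drought changed the leaf transcriptome in each genotype. Of the 100 genes most abundant by their mean over all 24 libraries, 78 fell and 13 rose in the libraries labelled WT, with a median log2 change of -0.98. In UBQ 84 fell (median -2.51), in DREM 85 fell (median -2.19) and in DEH2 83 fell (median -1.38). This depends on the ranking: of the 100 genes most abundant in the drought libraries of the genotype itself, 51 fell and 30 rose in WT (median -0.17), 25 fell and 66 rose in UBQ (median 1.33), 37 fell and 55 rose in DREM (median 0.47), and 57 fell and 41 rose in DEH2 (median -0.67). Of those most abundant in its well-watered libraries, 92 fell in WT, 98 in UBQ, 94 in DREM and 92 in DEH2. Either ranking favours genes that are higher in the libraries used for it. The most abundant gene over all libraries, TraesCS4A02G177500, held 1.24% ± 0.026 (SD, n = 3) of the normalized total in WT well-watered and 1.01% ± 0.13 (SD, n = 3) in WT drought. In UBQ it went from 1.25% ± 0.018 (SD, n = 3) to 0.0828% ± 0.0058 (SD, n = 3). Its log2 change with drought was -0.48 in WT, -4.48 in UBQ, -3.35 in DREM and -2.57 in DEH2, each with a standard error of 0.05. The next most abundant genes, TraesCS4D02G135000 and TraesCS4B02G140300, moved alike, by -0.71 and -0.53 in WT and by -5.48 and -4.77 in UBQ.

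At an adjusted p under 0.05 (limma, Benjamini-Hochberg) 36894 of 60088 genes changed with drought in WT, 18147 of them higher and 18747 lower. The counts were 43769 in UBQ, with 22361 higher and 21408 lower, 41409 in DREM, with 21167 higher and 20242 lower, and 41830 in DEH2, with 21096 higher and 20734 lower. Changes of at least 2-fold were called for 17515 genes in WT, 26080 in UBQ, 22726 in DREM and 23337 in DEH2. Across the 4 genotypes 9792 genes rose in all and 10171 fell in all, while 8971 were called in opposite directions in at least 2 of them. The median change over all tested genes stayed within 0.0334 log2 units of 0 in every comparison of this study. The authors' scaling tends to hold this median near 0 and higher and lower calls in balance. A general rise or fall of transcripts could therefore not be seen. On the first principal component, with 58.9% of the variance, the well-watered groups lay between -196.7 and -177.6, and the drought groups at 79.0 for WT, 194.7 for DEH2, 202.7 for DREM and 263.6 for UBQ.

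**Figure D2:**
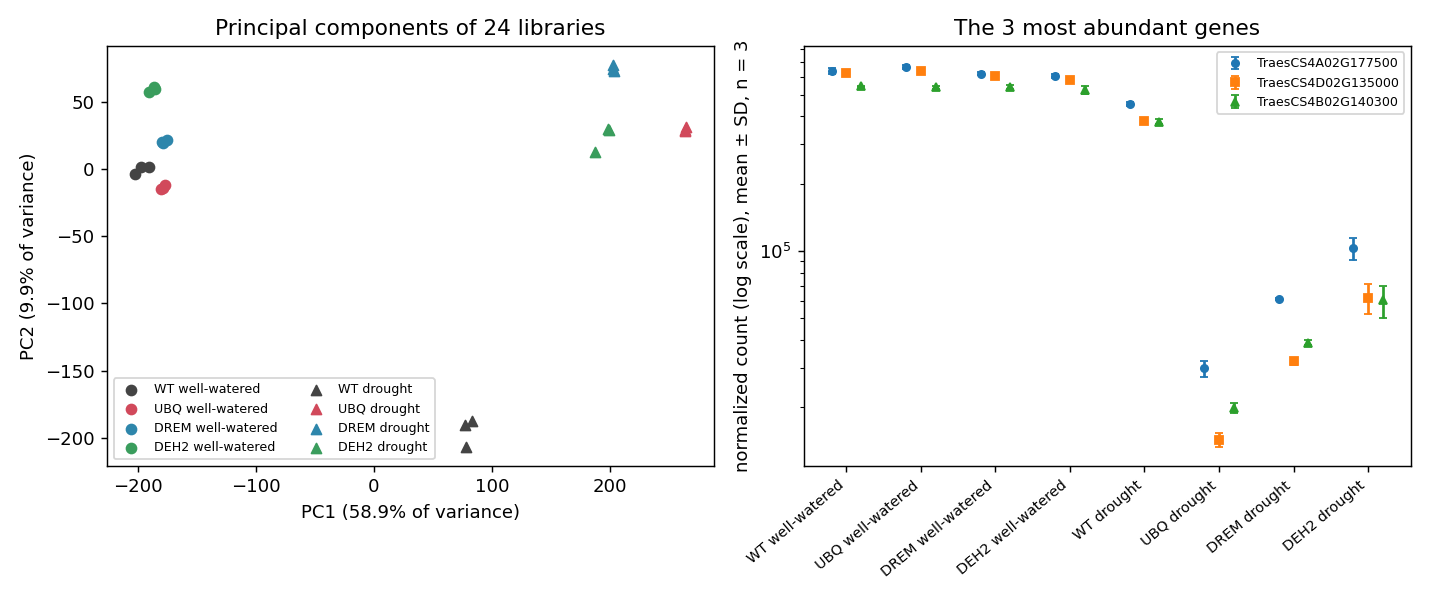
Left: the 24 libraries on the first 2 principal components of log2 values (axes give the percent of variance; circles well-watered, triangles drought). Right: normalized counts on a log scale of the 3 most abundant genes, mean ± SD of 3 libraries. The drought libraries labelled WT lie apart from the other drought libraries on both components, and TraesCS4A02G177500 falls from 638400 to 456300 in WT and from 666700 to 29870 in UBQ.

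Genes with the largest changes under drought were close to silent in 1 regime. In WT, TraesCS6A02G350500 was at 0 in all 3 well-watered libraries and at 21670 ± 2100 (SD, n = 3) under drought, at least 4840-fold higher when set against a floor of 3 reads per library (limma adjusted p = 1.8e-21). TraesCS5A02G153900 rose from 7.51 ± 3.78 (SD, n = 3) to 122900 ± 4310 (SD, n = 3). TraesCS5B02G014700 fell from 2288 ± 38.5 to 2.28 ± 2.08 (SD, n = 3 each) and TraesCS1D02G338100 from 6403 ± 640 to 6.50 ± 0.915 (SD, n = 3 each). In UBQ, TraesCS6B02G383500 and TraesCS6D02G332900 rose from 0 to 39380 ± 959 and 23970 ± 713 (SD, n = 3), at least 10700-fold and 6500-fold. TraesCS6D02G332900 also rose in DREM, to 6749 ± 219 (SD, n = 3), at least 2220-fold, and TraesCS6B02G383500 in DEH2, to 2800 ± 271 (SD, n = 3), at least 959-fold. Both genes with the largest fall in DREM, TraesCS1B02G075200 and TraesCS1B02G046300, lie in the 1B segment. In DEH2, TraesCS5B02G212000 fell to 0 in all 3 drought libraries, at least 757-fold lower.

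The segments entered these counts. With drought, 1275 of the 1939 tested genes of the 2A segment fell in WT and 167 rose (median -0.86), whereas in UBQ 371 fell and 1166 rose (median 0.82). Of the 328 tested genes of the 1B segment 278 fell in DREM (median -4.07) and 278 rose in DEH2 (median 4.01). Of the 365 of the 6B segment 297 fell in UBQ (median -3.55), and of the 166 of the 4B segment 118 rose in UBQ (median 1.19). In WT drought, replicate 1 had 29.0% of its normalized total in its 50 most abundant genes, against 12.6% in each of its sister libraries. A set of 174 genes was at least 4-fold above both sisters in this library and made up 22.3% of its total, against 0.847% and 0.653% in the sisters; counting error (Wilson 95% interval on the estimated reads) is at most 0.013 percentage points either way. At least 2-fold changes numbered 17246 in WT without this library.

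**Figure D3:**
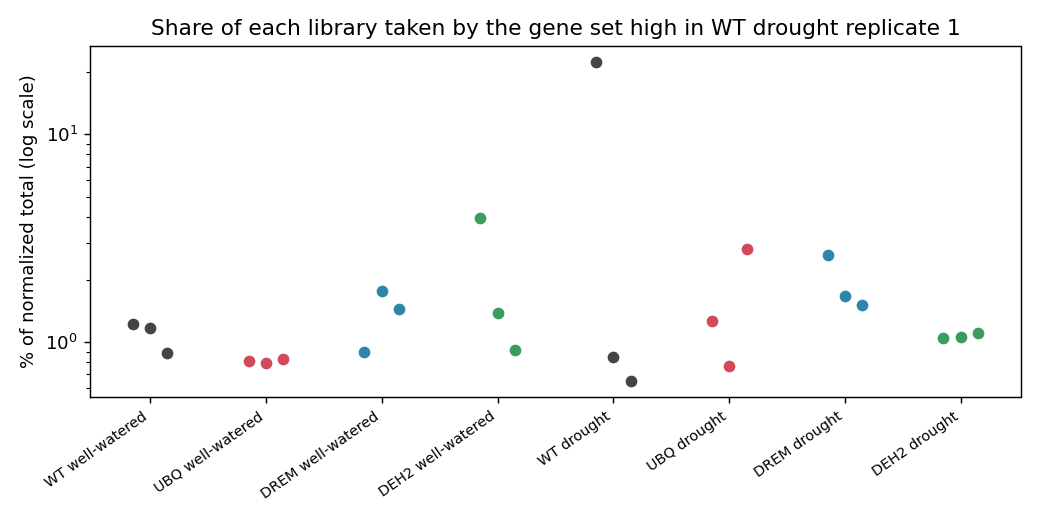
Percent of the normalized total, on a log scale, taken in each of the 24 libraries by the 174 genes at least 4-fold above both sister libraries in WT drought replicate 1; each point is 1 library. WT drought replicate 1 lies at 22.3%, DEH2 well-watered replicate 1 at 3.94%, and all other libraries at or below 2.81%.

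The third question was how each TOR line differed from WT in well-watered plants. The 3 most abundant genes differed little, with TraesCS4A02G177500 at 638400 ± 19200 in WT, 666700 ± 13000 in UBQ, 620800 ± 9240 in DREM and 607100 ± 11700 in DEH2 (SD, n = 3 each). Of the 100 genes most abundant over all libraries, 47 were higher and 15 lower in UBQ, 7 higher and 64 lower in DREM, and 16 higher and 19 lower in DEH2. In all, 18661 genes differed in UBQ (9105 higher, 9556 lower), 12813 in DREM (5806 higher, 7007 lower) and 11706 in DEH2 (5396 higher, 6310 lower; limma, adjusted p under 0.05). Differences of at least 2-fold were fewer, at 5894, 2969 and 3820 genes, and there the majority was higher: 3120 higher and 2774 lower in UBQ, 1633 and 1336 in DREM, and 2053 and 1767 in DEH2.

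Of the 1939 tested genes of the 2A segment 1259 were lower and 61 higher in UBQ (median -0.81). In DEH2 267 of the 328 tested genes of the 1B segment were lower and 1 was higher. In DREM no segment was shifted, with 206 genes of the 2A segment higher and 233 lower (median 0.00). The genes with the largest differences were near the floor of detection in 1 of the groups. TraesCS6A02G132500 was at 0 in WT and at 203.1 ± 154 (SD, n = 3) in UBQ, at least 45.4-fold higher, and TraesCS3B02G091400 was at 0 in UBQ, at least 71.3-fold lower than in WT (limma adjusted p = 2.83e-15). In DREM, TraesCS6A02G326200 was higher, at 442.4 ± 53.5 (SD, n = 3), 51.7-fold above WT, and TraesCS2B02G200800 was at 0, at least 44.9-fold lower. In DEH2, TraesCS7A02G021700 was higher, at 2036 ± 251 (SD, n = 3), 459-fold above WT. TraesCS2D02G586200 was at 1472 ± 179 (SD, n = 3) in DEH2 against about 2.96 reads summed over the 3 WT libraries, a ratio of 1010 with a 95% counting interval from 345 to 4890. The genes with the largest falls in DEH2 were TraesCS1B02G084700, the identifier next to the 1B segment, and TraesCS1B02G075200 within it.

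Some genes were called in more than 1 line. UBQ and DREM had 4175 genes called in the same direction, UBQ and DEH2 5861, and DREM and DEH2 5370, and 1387 genes were higher and 1452 lower in all 3. Opposite calls numbered 2268 for UBQ and DREM, 817 for UBQ and DEH2 and 374 for DREM and DEH2. Independent lists of these sizes would share 1994, 1821 and 1257 genes in the same direction and 1985, 1814 and 1239 in opposite directions. The correlation of the log2 differences across genes was 0.288 for UBQ and DREM, 0.452 for UBQ and DEH2 and 0.431 for DREM and DEH2. In 20 simulations of unchanged lines all libraries, WT included, were drawn around the WT means of their regime with the spread of the fit. They carry no deviations of the actual WT libraries. Shared controls alone gave about 0.50 for each pair, above all 3 of these correlations. The correlations cannot be judged against this value, because real differences widen the spread and lower the part due to controls. In the simulations 0 genes were called in the same direction for any pair. The covariances, 0.132, 0.272 and 0.203, compare with 0.047 in the simulations. With 3 WT libraries the controls could not be split, so part of the excess over independent lists may come from them. Genes are not independent replicates in these correlations.

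The fourth question was how the lines differed from WT under drought. Of the 100 genes most abundant over all libraries 77 were lower in UBQ (median log2 difference -1.24) and 81 in DREM (median -1.28), while in DEH2 40 were lower and 37 higher (median -0.09). Of those most abundant in the drought libraries of the line itself, 33 were lower and 53 higher in UBQ (median 0.28), 46 lower and 34 higher in DREM (median -0.36), and 24 lower and 59 higher in DEH2 (median 0.26). Of those most abundant in WT drought, 79 were lower and 2 higher in UBQ, 81 and 0 in DREM, and 53 and 19 in DEH2. Ranking in 1 of the compared groups favours genes that are higher in that group. TraesCS4A02G177500 stood at 456300 ± 10400 in WT, 29870 ± 2430 in UBQ, 60880 ± 504 in DREM and 102900 ± 11600 in DEH2 (SD, n = 3 each). The number of genes that differed was 36610 in UBQ (18391 higher, 18219 lower), 35368 in DREM (17161 higher, 18207 lower) and 34865 in DEH2 (17027 higher, 17838 lower; limma, adjusted p under 0.05). At least 2-fold differences were called for 17112, 16053 and 15432 genes.

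Among the genes with the largest differences, TraesCS5D02G388700 was at 1442 ± 60.2 (SD, n = 3) in UBQ, 1090-fold above WT, and TraesCS4B02G348200 was at 720.3 ± 168 (SD, n = 3) in UBQ and at 0 in WT, at least 212-fold higher. TraesCS5D02G447900 reached 6806 ± 439 (SD, n = 3) in DREM, 1210-fold above WT, and TraesCS2A02G166600 reached 977.4 ± 71.9 (SD, n = 3) in DEH2, 649-fold above WT. The 1090-, 1210- and 649-fold ratios rest on about 4, 17 and 4.59 reads summed over the WT drought libraries, so they are rough. The largest falls in UBQ, TraesCS6B02G023900 and TraesCS6B02G022500, lay in the 6B segment, and those in DREM, TraesCS1B02G046300 and TraesCS1B02G036500, in the 1B segment. In DEH2, TraesCS5D02G266000 was lower at 19.5 ± 33.1 (SD, n = 3). The 2A segment, low in WT drought, was higher in all 3 lines, with 1289 of 1939 genes called higher in UBQ, 1282 in DREM and 1278 in DEH2. In UBQ 293 of the 365 tested genes of the 6B segment were lower and 111 of the 166 of the 4B segment higher, and in DREM 279 of the 328 of the 1B segment were lower.

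Under drought UBQ and DREM shared 25212 genes called in the same direction, UBQ and DEH2 25563, and DREM and DEH2 24059, and 10168 genes were higher and 10330 lower in all 3 lines. Opposite calls numbered 1898, 1668 and 2088. Independent lists would share 10773, 10620 and 10268 in the same direction. The covariances of the log2 differences were 1.207, 1.214 and 1.090, against 0.047 with simulated unchanged lines, and the correlations 0.696, 0.738 and 0.708 against 0.499, 0.498 and 0.499. The 3 comparisons again share the WT libraries, which include replicate 1 with its separate gene set. The simulations did not use these libraries, and their correlations are again no measure for the observed ones.

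**Figure D4:**
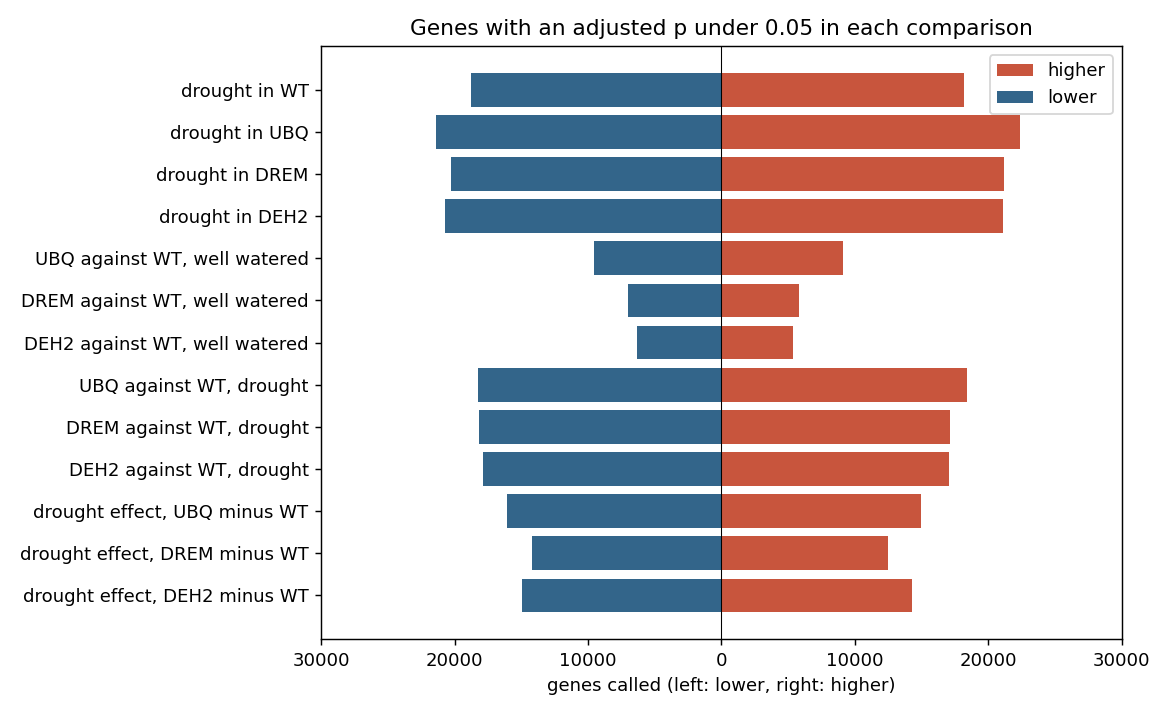
Number of genes called higher (right) and lower (left) in each of the 13 comparisons at an adjusted p under 0.05 among 60088 tested genes. The largest count is for drought in UBQ, 43769 genes, and the smallest for DEH2 against WT in well-watered plants, 11706.

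The last question was whether the response to drought differed between each line and WT, tested as the difference of the drought effects. It differed for 31045 genes in UBQ (14937 with a more positive change than in WT, 16108 with a more negative one), for 26687 in DREM (12456 and 14231) and for 29233 in DEH2 (14270 and 14963; limma, adjusted p under 0.05). The test takes both groups of a label as the same plant material. Any difference in material between them would enter these counts, also outside the segments, and cannot be told apart from a differing response. Among the 100 genes most abundant over all libraries the change was more negative in UBQ for 75 and more positive for 14. In DREM it was more negative for 75 and more positive for 11, and in DEH2 for 43 and 28. Among those most abundant in the drought libraries it was more negative for 57, 59 and 37 and more positive for 23, 23 and 30. Of the 30682 genes with a differing effect in UBQ that were called with drought in WT or UBQ, 17793 were called in both. Of these 10217 changed more in UBQ in the same direction, 3090 changed more in WT in the same direction, and 4486 were called in opposite directions; 8948 genes were called in UBQ only and 3941 in WT only. In DREM 14913 of 26368 genes were called in both, with 7615, 3696 and 3602 in these classes, and in DEH2 16217 of 28892, with 8045, 3866 and 4306.

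TraesCS2D02G425300 was among the genes with the most different response in both UBQ and DEH2. It rose under drought to 3079 ± 535 in UBQ and to 1701 ± 111 in DEH2, and in WT it stood at 79.3 ± 60.9 well-watered and 6.32 ± 5.95 under drought (SD, n = 3 each). TraesCS5D02G447900 rose in DREM from 8.60 ± 6.44 to 6806 ± 439, and in WT it went from 41.3 ± 13.5 to 5.61 ± 7.23 (SD, n = 3 each). TraesCS2B02G200800 fell in UBQ from 3961 ± 619 to 0.615 ± 1.06, and rose in WT from 136.1 ± 27.0 to 850.7 ± 226 (SD, n = 3 each). In the 2A segment 1456 of 1939 genes had a more positive change in UBQ than in WT (median difference 1.67), 1112 in DREM and 1102 in DEH2. In UBQ the change was more negative for 270 of the 365 genes of the 6B segment and more positive for 96 of the 166 of the 4B segment. In the 1B segment 263 of 328 genes had a more negative change in DREM than in WT, and 267 a more positive change in DEH2.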

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

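The tests of labels exchanged between groups and of drought as the source of the chromosome segments were chosen after the result was seen. So were all counts of other splits. The permutation tests of the segments were chosen after the segments had been seen. The other tests were set down before their results.

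The drought effect differed from that of WT for 31045 genes in UBQ, 26687 in DREM and 29233 in DEH2, by limma's test of the difference. That test takes both groups of a label as the same plant material. When the 12 libraries of each comparison were divided in 100 ways, the real one included, 2 gave as many genes for UBQ (highest other 32150), 6 for DREM (highest other 32066) and 2 for DEH2 (highest other 30345). All of the divisions with as many genes kept the 3 drought libraries of each genotype together, so they retain the large difference between genotypes under drought, a structure of the samples. Those that divided these libraries mixed unlike ones and gave at most 3825, 1695 and 2170 genes, so they are no measure of chance. Of the 15 drawn with the drought libraries kept together, the real one included, 2, 6 and 2 gave as many genes, and only 20 such divisions exist, too few for a share under 0.05. For the 10 comparisons of 3 against 3 libraries the splits number 10, too few for a share under 0.05; the real split was the 1 with the most genes in each. The highest count of another split was 1 for drought in WT (36894 genes), 0 in UBQ (43769), 1 in DREM (41409) and 0 in DEH2 (41830). It was 169, 10 and 15 for UBQ, DREM and DEH2 against WT in well-watered plants (18661, 12813 and 11706 genes), and 2 in each of the same comparisons under drought (36610, 35368 and 34865).

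Measured per library as the median over the genes in the scan's windows, a narrower set than all tested genes of a segment, and relative to the median of the 4 groups of the same regime, the drought effect on the 2A segment was -0.77 log2 units in WT and 0.83 in UBQ, a difference of 1.60, and on the 1B segment -5.03 in DREM and 5.30 in DEH2, a difference of 10.3. Both differences had an exact two-sided permutation p of 0.005 over 400 relabellings of 12 libraries, the smallest they can give, for segments picked because they moved. Against a drought response of these 2 segments, they were low in well-watered groups, by -0.77 at the weaker. For the 4B and 6B segments the well-watered median farthest from 0 was -0.05. Over all tested genes the 6B segment changed with drought by -0.13 in WT, -0.06 in DREM and -0.11 in DEH2, against -3.55 in UBQ. The 4B segment changed by 0.02, 0.15 and 0.21, against 1.19 in UBQ. These values argue against a drought response of this size common to the genotypes. A drought response of UBQ alone and the plant material of UBQ drought cannot be told apart, since 1 group carries both. Altered copy number of chromosome segments is a candidate explanation, not separated here from other causes that act on a whole segment. Segment genes too low in expression for the scan lay on the segment's side in at least 78.0% of cases in every carrying group. In any other group it was at most 61.6%. This shows that the shift is regional, which any such cause would give. Exchanged labels alone, between lines that are each uniform, would place every segment in both regimes, but 2 of the 4 were in 1 regime. For part of the pattern an exchange stays open: outside all segments the deviations of DEH2 well-watered correlated across genes with DREM drought at 0.383 and with DEH2 drought at -0.186, with the first higher on 21 of 21 chromosomes. On the other side of this exchange DREM well-watered correlated with DEH2 drought at 0.175 and with DREM drought at -0.089, again with the first higher on 21 of 21. But WT well-watered correlated with DEH2 drought at 0.196, higher still. These deviations were taken from the mean of the 4 groups of a regime, so they sum to 0 for each gene. Expression shared by DEH2 well-watered and DREM drought alone would therefore lower the correlations of the other well-watered groups with DREM drought. Those of WT and UBQ were -0.203 and -0.078. The other side may thus follow from the first and is no second support for an exchange. An exchange of UBQ and WT is argued against. WT well-watered correlated with UBQ drought at -0.134 and with WT drought at 0.109, with the own label higher on 21 of 21 chromosomes. Once the mean drought effect and the mean level of each gene were removed, the values were -0.085 and 0.056, with UBQ drought higher on 0 of 21. The other side of this exchange decides less. UBQ well-watered correlated with WT drought at 0.052 and with UBQ drought at 0.138, with the own label higher on 18 of 21. After the same removal the values were 0.09 and 0.122, with WT drought higher on 7 of 21. A wrong label on 1 of these groups needs no such partner and stays open. The chromosomes were measured in the same libraries of each group, so agreement between them is not replication. Plants of 1 label that differ in chromosome constitution may give the same picture, and nothing in the labels tells which seed or plant each group came from.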

How the results depend on the processing

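Each of the 13 counts of changed genes stayed within 1.5 times its value under both other pseudocounts, both other filters, TMM factors, quantile normalization, limma without the trend, fits of only the compared libraries, and without the genes of the 4 segments, an alternative chosen after seeing the data. Higher and lower calls were close to balanced, and which of them was the majority is not stable: it turned in 12 of the 13 comparisons under at least 1 setting, in 6 under quantile normalization, in 5 with TMM factors, in 10 at a minimum of 2-fold, and the share of higher calls moved by at most 9.7 percentage points. A minimum of 2-fold lowered all counts by construction. It left 17515, 26080, 22726 and 23337 genes for drought in WT, UBQ, DREM and DEH2, and 5894, 2969 and 3820 for UBQ, DREM and DEH2 against WT in well-watered plants. Under drought it left 17112, 16053 and 15432, and for the differences of the drought effect 17294, 13454 and 15489. The genes that UBQ and DREM, UBQ and DEH2, and DREM and DEH2 shared against WT then numbered 1035, 1717 and 1184 in well-watered plants and 10403, 10502 and 9834 under drought. Leaving out 1 library of the compared groups at a time moved no count by over 1.5 times; for DREM against WT in well-watered plants, the count that moved most, the range was 9903 to 11974. All 946 values of named genes under the alternatives kept their direction and stayed past the threshold. Of the segments' medians in the 13 comparisons 579 moved by less than the spread between replicates and 65 by more; a further 260 belong to settings that move no median by construction (no filter, no trend, only the compared libraries, the replicate block, a minimum of 2-fold). In all, 20 changed sign, each within 0.09 of 0 to begin with. The size of the strong shifts depends on the pseudocount and the filter: with drought the 1B segment moved by -2.79 in DREM and 2.75 in DEH2 with a pseudocount of 5, and by -5.23 and 5.24 with the filter of 50, against -4.07 and 4.01 with the settings used; the 6B segment in UBQ moved by -2.38 and -4.57 in place of -3.55.

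Replicate numbers were not taken to pair the samples, since the deviations of same-numbered libraries correlated at only -0.0492 to 0.124. Not every library correlated best with its own number, but 14 of the 24 did, against a mean of 7.88 when the libraries were renumbered at random within their groups; 41 of 1000 such renumberings gave as many, so a weak link through the numbers is not ruled out. With the replicate block 36795 genes changed with drought in WT and 43689 in UBQ, and no other count moved by over 1.5 times. The change of the 100 most abundant genes depends on the libraries used to rank them, an alternative chosen after seeing the data. With drought its median was -2.51 in UBQ when ranked over all libraries, 0.02 when ranked in the drought libraries and 1.33 in those of UBQ, and in DREM it was -2.19 over all libraries and 0.47 in the drought libraries of DREM. For UBQ against WT under drought it was -1.24, against 0.28 when ranked in UBQ drought and -1.43 when ranked in WT drought. Only 47 genes were in both the well-watered and the drought ranking. Count models were planned for the case that whole reads could be recovered, and were not run, as they could not. Other settings for TOR and for the gene lists gave no values, because no identifier matched a name. Estimated depths of 33700000 to 55300000 reads limit the lowest genes, where 3 reads are worth up to a value of 4.63.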

Other observations

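The tests in this part were set down before their results were seen; the patterns they bear on were noticed in the same data, and for the carry-over test the mean over 100 random parts replaced a single part after that one had been seen, and the counts among genes called in both genotypes were chosen after the result was seen.

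A further 100 genes were under 3 reads in every well-watered library of all 4 genotypes and at 30 or more in every drought library, and 10 genes showed the opposite. The shares of tested A, B and D genes that rose with drought were 28.6%, 30.6% and 31.7% in WT, 38.9%, 36.2% and 36.9% in UBQ, 35.8%, 34.4% and 35.8% in DREM, and 35.1%, 35.8% and 34.8% in DEH2. Those that fell were 34.1%, 29.9% and 29.8% in WT, 34.6%, 36.3% and 36.0% in UBQ, 33.4%, 34.2% and 33.7% in DREM, and 34.97%, 33.4% and 35.2% in DEH2; differences between subgenomes were not tested. On chromosome 2A 52.98% of the tested genes fell in WT with drought, and on chromosomes 2B and 2D 31.2% and 31.5%.

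The gene set high in WT drought replicate 1 held 174 genes with a median of 5.04 log2 units above the sister libraries, and 47 of them had identifiers with no assigned chromosome (U), a class that makes up 2.49% of all identifiers. TraesCSU02G056800, the most abundant, stood at 3274000 in replicate 1 and at 107800 and 80370 in the other two. Among the set's 161 tested genes as few as 0.6% rose with drought in 1 of the 3 lines and at most 1.9% in any. Those that fell made up 1.9% in UBQ, 5.6% in DREM and 5% in DEH2. These shares cannot decide on a response to drought, because the genes were chosen for a large spread within 1 group. That spread enters the error of every comparison in the single fit and leaves few calls in either direction. A candidate explanation is carry-over of 1 class of RNA that varies between libraries. In the other 7 groups, the library highest in a random part of the set was also highest in a median of 68.5% of the remaining genes. The share ran from 35.1% to 96.2% across groups, against 31.3% to 44.1% among other genes. In UBQ well-watered it was 35.1% against 32.6%. Any class of genes that varies together between libraries would give this, so the test does not single out carry-over. Genes of the set also stood out in DEH2 well-watered replicate 1, where 20 of the 22 genes at least 4-fold above both sisters belonged to the set.

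The response to drought at 2-fold or more was wider in each line than in WT, by 1.3 times in the line with the fewest genes. The genes inside the segments are not the whole source, since this ratio was 1.31 without them, and neither is WT drought replicate 1, as it was 1.32 without that library. Leaving these genes out does not remove differences outside the segments between the plants of the groups, so it cannot decide on the plant material as a source. A single response that is merely stronger in the lines is also argued against, because at most 47.6% of the genes with a differing effect changed more in the line in the same direction, by the sign of the estimates; among those called in both genotypes it was 10217 of 17793 genes in UBQ, 7615 of 14913 in DREM and 8045 of 16217 in DEH2. Whether the plants labelled WT had lost less water when sampled stays open, since plant water status is not given, and so does the identity of the WT drought plants, in which the 2A segment was lower, while in WT well-watered plants it was not.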
